A study of Polistes metricus with 16 samples.

How the data were processed

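Brain RNA from 16 adult female Polistes metricus paper wasps was sequenced, with 1 library per wasp and 4 wasps in each of 4 groups. Per the labels' protocols, total RNA was extracted from individual brains, and 1 µg per wasp went into libraries made with an Illumina TruSeq RNA kit. Whether that kit version or the counting kept the strand is not given in the sources used here. Per the submitters' processing notes, the tools named were Trimmomatic 0.32, Bowtie2 and eXpress, without their options or order. The transcript set that was counted against, and the treatment of reads shared between similar transcripts, are not given in the sources used here.

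The authors deposited 1 table of whole-number counts, with 127674 transcript identifiers and a column for each of the 16 wasps. eXpress can give estimated counts, and whether these whole numbers are reads counted directly or estimates that were rounded is not given in the sources used here. They were used as deposited, as counts without normalization, and their totals differed between libraries. Columns were joined to groups through the wasp number that both the column name and the sample label carry. No column belonged to any other sample. The table does not pair its identifiers with gene names, and no reference genome or annotation was used here. Values are therefore given per transcript identifier, and sums per gene, gene lists and gene set tests were not run. Neighbouring identifiers can be fragments or variants of the same gene, so a count of transcripts is not a count of genes.

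Total counts ran from 14949149 to 22832434 per library, with a median of 18994600. Transcripts were tested if they passed edgeR's filterByExpr with its default minimum count of 10, which kept 55226 and left out 72448. The tested transcripts held 99.3% to 99.6% of the counts of each library. Libraries were scaled by TMM, with factors from 0.853 to 1.08. The common biological coefficient of variation was 21.4%.

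Differences were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test with robust estimation. All 16 libraries entered 1 fit with a mean for each of the 4 groups, which left 12 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method. A transcript is said to be called where its adjusted p lies under 0.05. The contrasts were foundresses trained to faces against foundresses trained to patterns, workers from allospecific against conspecific nests, the mean of both worker groups against foundresses trained to faces, and any difference among the 4 groups. No covariate was fitted, because the month of collection goes with the training stimulus and nearly with caste, and the labels name no sequencing batch. The standard error of a log2 fold change was taken as its size divided by the square root of its F statistic. CPM values are deposited counts divided by the library size after TMM scaling, in the usual CPM unit.

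Whole profiles were compared by the share of the summed squared distance between libraries that lies between groups, on log2 CPM with a prior count of 2. Its p-value comes from an exact permutation test over every split of the wasps into groups of the same sizes. Pairs of libraries within a group were compared for duplicates. The 24 pairs had a chi-square of 7.14 to 55.4 per degree of freedom, so none agreed within sampling noise. Between groups the closest pair was MW42 and MW32, at 5.97. Each library was treated as 1 replicate, and the birth nest and host nest of single wasps did not enter the tests. Pearson correlations of log2 CPM within groups ran from 0.944 to 0.976.

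The statistics were tested on simulated data with known changes in 200 transcripts, of which some changed by 1.5-fold, some by 2-fold and some by 4-fold. For foundresses trained to faces against patterns, with 54358 simulated transcripts tested, 2.99% of the 1.5-fold, 47.8% of the 2-fold and 86.4% of the 4-fold changes were called, with 10 false calls. For allospecific against conspecific nests, with 54378 simulated transcripts, these shares were 5.97%, 47.8% and 78.8%, with 4 false calls. For workers against foundresses trained to faces, with 54240 simulated transcripts, they were 14.9%, 50.7% and 93.9%, with 7 false calls. Simulated transcripts were drawn independently of each other, whereas real transcripts varied together across libraries. The false calls of the simulation therefore do not show how many arise in the real data. There, a split of the workers that crossed the nests gave up to 501 calls.

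The comparisons, their tests, the rule for naming transcripts and most alternatives were chosen before the data were examined. The transcripts to be named, where no gene names could be had, were the 2 with the lowest p among those that rose and the 2 with the lowest p among those that fell, in the comparison with the most calls. The alternatives were DESeq2 1.42.0 median-of-ratios factors, the DESeq2 test itself, limma 3.58.1 voom with and without sample quality weights, no low-count filter, a filter at 50 counts in 4 libraries, estimation without the robust option, a surrogate variable from sva 3.50.0, a fit of the compared groups alone, a threshold of 0.1, and leaving out each wasp in turn. For whole profiles they also included Spearman distance and a prior count of 5. Alternatives chosen after seeing the data were leaving out a set of abundant transcripts that vary together, keeping 1 transcript per run of neighbouring identifiers that vary together, and taking both foundress groups as the reference.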

Results

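Polistes metricus is a paper wasp in which overwintered queens, called foundresses, start nests in spring and later rear daughters that serve as workers. The study asked which transcripts in the brain differ with learning of visual stimuli, with social rearing and with caste. Wasps were trained in a T-maze with negative reinforcement over 40 trials and killed 30 minutes after the last. The stimuli were simple patterns or faces of the related species Polistes fuscatus. The 4 groups of 4 wasps were foundresses trained to patterns, foundresses trained to faces, workers kept on a nest of their own species that was not their birth nest, and workers kept on a nest of P. fuscatus (allospecific). Both worker groups had spent at least a week on that nest and were trained to faces. Foundresses trained to patterns were collected in May and those trained to faces in June. Of the 8 workers, 1 (MW21) was collected in June and 7 in July, so month cannot be told apart from stimulus among foundresses and hardly from caste.

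Counts, which may be rounded estimates of read numbers, totalled 20330839 ± 2373337 per library (SD, n = 4) in foundresses trained to patterns and 20160339 ± 2093941 (SD, n = 4) in foundresses trained to faces. They totalled 17537302 ± 1851868 (SD, n = 4) in workers from conspecific nests and 18235228 ± 1986781 (SD, n = 4) in workers from allospecific nests. The number of identifiers with at least 1 count averaged 93989 ± 4235 and 92656 ± 1143 in the respective foundress groups, and 86970 ± 3128 and 85156 ± 1452 in the respective worker groups (SD, n = 4 each). The first principal component of the 55226 tested transcripts held 19.6% of the variance and the second 15.2%. Along the first, wasps of every group were spread widely. On the second, the 8 workers lay from -64.8 to 2.71 and the 8 foundresses from -17.0 to 67.02.

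**Figure D1:**
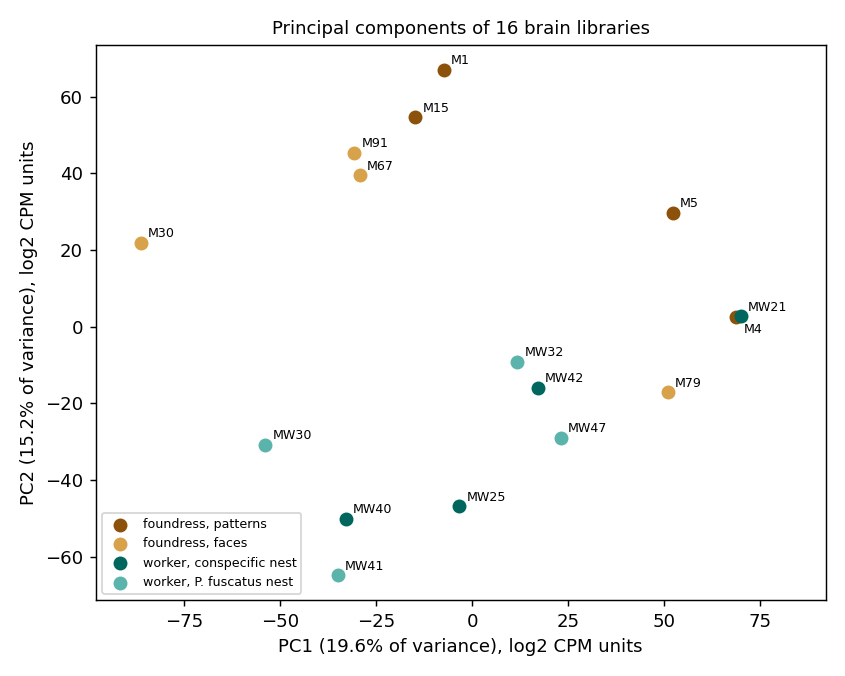
Position of the 16 libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, in log2 CPM units, with 1 labelled point per wasp coloured by group. Workers lie at -64.8 to 2.71 on the vertical axis and foundresses at -17.0 to 67.02, where M79 is the lowest foundress.

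A set of 143 transcripts took very different shares of the libraries. It was chosen after seeing the data because the log2 CPM of its members correlated above 0.9 with that of the most abundant identifier. The set is called abundant for its summed share, and the abundance of its members was no part of the choice. It held 13.3% ± 3.34 of all counts in foundresses trained to patterns, 7.93% ± 1.53 in foundresses trained to faces, 9.19% ± 7.16 in workers from conspecific nests and 5.64% ± 3.55 in workers from allospecific nests (SD, n = 4 each). The extremes were 2.18% in MW41 and 19.2% in MW21, an 8.82-fold range within workers.

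Foundresses trained to P. fuscatus faces were compared with foundresses trained to simple patterns to ask whether brain transcripts differ with the kind of visual stimulus learned. No transcript passed edgeR's quasi-likelihood test between these groups of 4, where the lowest adjusted p was 0.2, and limma-voom called 0 and DESeq2 139. Of the 55226 transcripts, 5673 (10.3%) had an unadjusted p under 0.05, against 2761 if p-values were uniform. The median size of the difference was 0.19 on the log2 scale, and its median standard error was 0.21, which leaves a 95% interval of 0.44 to either side. In 3396 transcripts (6.15%) the groups did not overlap, where chance gives 2.86%. The transcript PmetTSAr2.0-040168, named for its caste difference, stood at 40.2 ± 2.82 CPM in faces and 31.6 ± 1.84 CPM in patterns (SD, n = 4 each), with a log2 difference of 0.35 ± 0.11 (SE) and an edgeR adjusted p of 0.338. PmetTSAr2.0-053836 stood at 123 ± 11.7 and 154 ± 30.3 CPM (SD, n = 4 each), with a log2 difference of -0.32 ± 0.13 (SE) and an edgeR adjusted p of 0.436. The set of 143 abundant transcripts had a log2 share lower by 0.73 (difference -0.732) in faces, with an exact two-sided permutation p of 0.0571 and an adjusted p of 0.152 over 4 such tests.

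Whole profiles of the 8 foundresses did not separate by stimulus beyond the spread between wasps. The stimulus accounted for 17.9% of the squared distance, and 7 of the 35 splits gave as much (exact permutation p = 0.2, where 0.0286 is the smallest possible). Other settings called some transcripts, with 139 by DESeq2 (102 higher in faces), 33 with no low-count filter (24 higher), 11 without M79 and 1 without M67. The simulated tests, with changes in only 200 transcripts, called 2.99% of 1.5-fold and 47.8% of 2-fold changes at this number of wasps. Small differences could therefore have been missed here, and recovery where more transcripts change was not simulated.

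**Figure D2:**
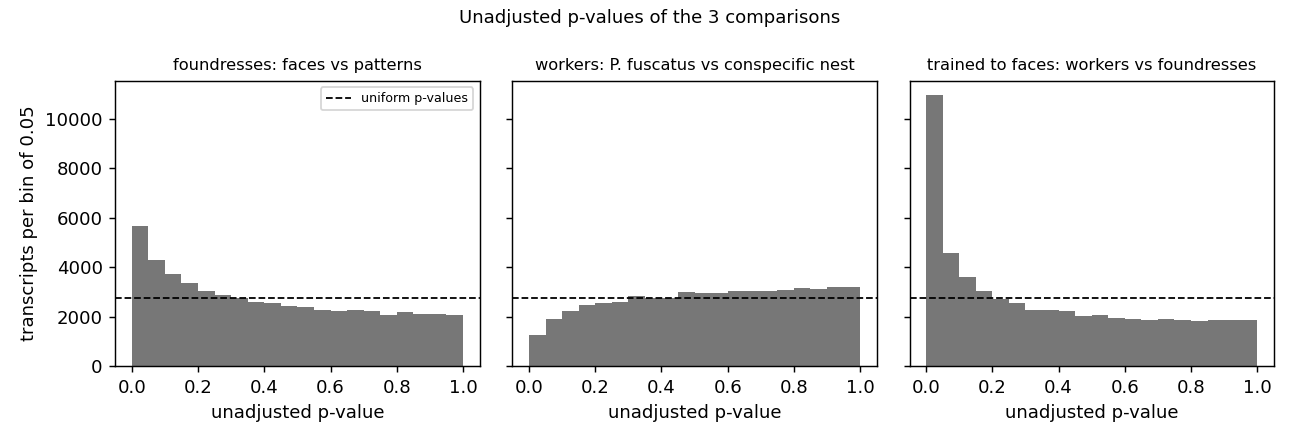
Histograms of unadjusted p-values (horizontal axis) against the number of the 55226 tested transcripts in each bin of 0.05 (vertical axis) for the 3 comparisons, with a dashed line at the height of uniform p-values. The lowest bin holds 5673 transcripts for faces against patterns, 1264 for allospecific against conspecific nests and 10965 for workers against foundresses trained to faces.

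Workers kept on P. fuscatus nests were compared with workers kept on conspecific nests to ask whether the social surroundings of the adult leave a mark on brain transcripts. No transcript passed edgeR's quasi-likelihood test, where the lowest adjusted p was 1, and limma-voom called 0 and DESeq2 1. At an unadjusted p under 0.05 there were 1264 transcripts (2.29%), fewer than the 2761 of uniform p-values. The median size of the difference was 0.13 on the log2 scale, with a median standard error of 0.21 and a 95% interval of 0.45 to either side. Groups did not overlap in 893 transcripts (1.62%), where chance gives 2.86%. For each of the 4 transcripts named for their caste difference the edgeR adjusted p was 1. PmetTSAr2.0-053836 was at 290 ± 30.8 CPM on allospecific and 314 ± 9.68 CPM on conspecific nests, and PmetTSAr2.0-053842 at 79.7 ± 14.5 and 84.2 ± 5.73 CPM (SD, n = 4 each). PmetTSAr2.0-040168 was at 21.1 ± 2.56 and 21.2 ± 1.80 CPM, and PmetTSAr2.0-020258 at 5.35 ± 0.537 and 5.70 ± 1.41 CPM (SD, n = 4 each). The abundant set of 143 transcripts differed by -0.615 in log2 share, allospecific minus conspecific, with an exact two-sided permutation p of 0.457 and an adjusted p of 0.471.

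The nest accounted for 11.6% of the squared distance among the 8 workers, and 32 of the 35 splits gave as much (exact permutation p = 0.914, where 0.0286 is the smallest possible). Leaving out any of the 8 workers gave 0 calls by edgeR.

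Workers were compared with foundresses trained to the same faces, a comparison of caste together with age, season and rearing on a foreign nest. The 8 workers and 4 foundresses differed in 2060 transcripts (3.73% of those tested), of which 1230 were higher and 830 lower in workers. PmetTSAr2.0-053836 rose 2.45-fold, from 123 ± 11.7 CPM in foundresses trained to faces (SD, n = 4) to 302 ± 24.5 CPM in workers (SD, n = 8), and PmetTSAr2.0-053842 rose 2.21-fold, from 37.0 ± 3.43 to 81.9 ± 10.5 CPM. PmetTSAr2.0-040168 fell to 0.526 of its foundress level, from 40.2 ± 2.82 to 21.1 ± 2.05 CPM, and PmetTSAr2.0-020258 fell to 0.368 of it, from 14.98 ± 3.68 to 5.52 ± 1.0 CPM. In each of these 4, every worker lay beyond every foundress trained to faces.

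By edgeR's quasi-likelihood test the log2 fold change of PmetTSAr2.0-053836 was 1.29 ± 0.12 (SE) with an adjusted p of 6.58e-05, and that of PmetTSAr2.0-053842 was 1.15 ± 0.11 (SE) with an adjusted p of 6.58e-05. By the same edgeR test PmetTSAr2.0-040168 had -0.93 ± 0.09 (SE) with an adjusted p of 6.58e-05, and PmetTSAr2.0-020258 had -1.44 ± 0.17 (SE) with an adjusted p of 0.000247. Counts behind these values were 2222 to 7153 per library for PmetTSAr2.0-053836, 665 to 2114 for PmetTSAr2.0-053842, 308 to 904 for PmetTSAr2.0-040168 and 65 to 392 for PmetTSAr2.0-020258. Foundresses trained to patterns, which are no part of this contrast, stood at 154 ± 30.3 CPM for PmetTSAr2.0-053836, 42.3 ± 3.18 CPM for PmetTSAr2.0-053842, 31.6 ± 1.84 CPM for PmetTSAr2.0-040168 and 13.8 ± 2.61 CPM for PmetTSAr2.0-020258 (SD, n = 4). In all 4 their mean lay nearer to that of the other foundresses than to that of the workers. Values of the pair PmetTSAr2.0-053836 and PmetTSAr2.0-053842, whose identifiers lie 6 apart, correlated at 0.60 within groups, so both are uncertain as separate genes, and reads may be shared between them.

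**Figure D3:**
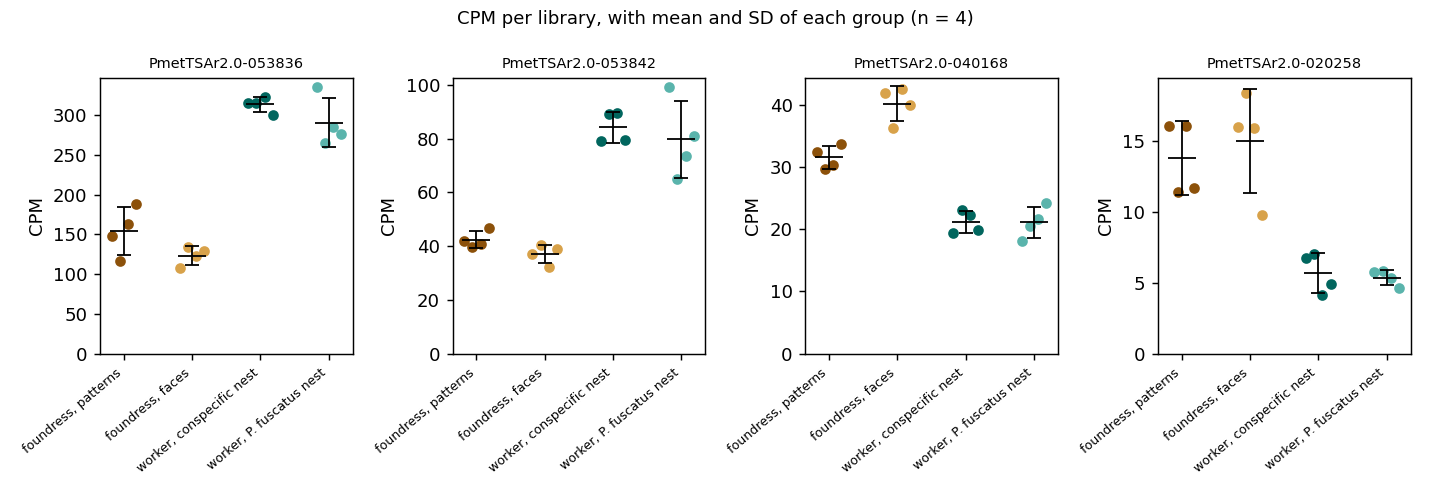
CPM (vertical axis, starting at 0) of the 4 named transcripts in each wasp, with 1 panel per transcript, 1 point per library, and the mean and SD of each group of 4 in black. In PmetTSAr2.0-053836 the 8 workers lie between 265 and 335 CPM and the 8 foundresses between 107 and 189 CPM.

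Most called differences were under 2-fold. The median log2 fold change was 0.64 among the 1230 transcripts higher in workers and -0.65 among the 830 lower in workers, which are folds of 1.56 and 0.636. At least a 2-fold difference was found in 159 transcripts higher and 221 lower in workers. Groups did not overlap in 2004 transcripts (3.63%), 1173 of them called, where chance gives 0.404%. Calls were more frequent among abundant transcripts, by 4 equal bins of mean log2 CPM. They rose from 220 (1.59%) in the lowest bin through 364 and 589 to 887 (6.42%) in the highest. The 1230 transcripts together held 3.71% ± 0.215 of the counts in workers (SD, n = 8) and 2.40% ± 0.313 in foundresses trained to faces (SD, n = 4). The 830 transcripts held 2.13% ± 0.176 in workers (SD, n = 8) and 3.21% ± 0.295 in foundresses trained to faces (SD, n = 4). Both sets were chosen on these libraries. In foundresses trained to patterns the same sets held 2.80% ± 0.334 and 2.47% ± 0.111 (SD, n = 4). Because transcripts with neighbouring identifiers can vary together, the 2060 were also joined into runs within which identifiers lay at most 3 apart and correlated above 0.7 within groups. They fell into 1714 runs, 1000 with higher and 714 with lower calls and 0 with both. The set of 143 abundant transcripts differed by 0.39 in log2 share, foundresses trained to faces minus workers, with an exact two-sided permutation p of 0.471.

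Whole profiles of the 12 wasps trained to faces separated by caste, which accounted for 16.3% of the squared distance (exact permutation p = 0.00404, 2 of 495 splits). The other of these 2 splits separated the wasps more, at 18.2%. The number of calls moved with single wasps, to 398 without M30, 639 without M91, 1196 without MW41, 1286 without MW42 and 1364 without MW25, and with settings, to 3536 by DESeq2, 4316 at an adjusted p under 0.1 and 1294 in a fit of these 12 wasps alone. The split of 1230 higher against 830 lower (59.7% higher) turned to 913 against 1106 (45.2% higher) with the 143 abundant transcripts left out before scaling and to 555 against 739 (42.9% higher) in the fit of 12 wasps, so which direction had more calls is not settled.

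**Figure D4:**
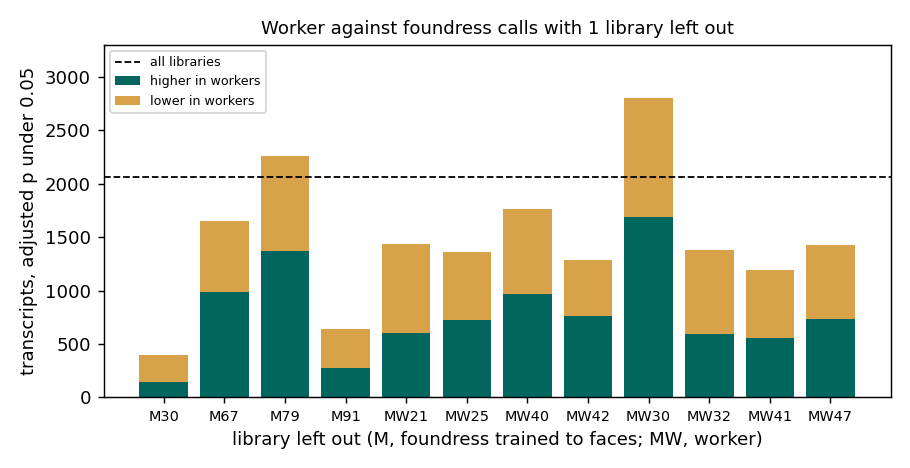
Number of transcripts called between workers and foundresses trained to faces (vertical axis) with each of the 12 wasps left out (horizontal axis), stacked as higher and lower in workers, with a dashed line at the 2060 calls of all libraries. The count falls to 398 without M30 and 639 without M91, and reaches 2803 without MW30.

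Each worker group was also set against each foundress group in the same fit. Workers from conspecific nests differed from foundresses trained to faces in 1747 transcripts (1245 higher, 502 lower), and workers from allospecific nests in 148 (65 higher, 83 lower). The direct test between these worker groups called 0 transcripts, so the unequal counts do not show that the nests differ. Against foundresses trained to patterns, workers from conspecific nests differed in 68 transcripts, workers from allospecific nests in 116, and both worker groups together in 395 (189 higher, 206 lower). With both foundress groups as the reference, an alternative chosen after seeing the data, 2031 transcripts differed (1191 higher, 840 lower in workers), 1289 of which were also among the 2060.

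Across all 4 groups, 540 transcripts (0.978%) differed by edgeR's quasi-likelihood test, with a lowest adjusted p of 0.000115. Of these, 484 were also called between workers and foundresses trained to faces, a contrast contained in this test. The count moved to 2419 by DESeq2, 1472 with no low-count filter, 1366 at an adjusted p under 0.1, 1181 with limma-voom sample quality weights and 1153 with a surrogate variable. It fell to 208 without M91, 221 without MW41, 229 without M30, 243 without MW25, 266 without MW40, 284 without M5, 297 without MW42, 312 without M1, 337 without MW21, and 354 without M15 or without MW32.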

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

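The tests of month and of exchanged labels were chosen only after the results they bear on were seen, as was the alternative that leaves out the abundant transcripts.

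The number of identifiers with a count was 82298 in MW40, far from the 88142 to 88836 of the other 3 workers from conspecific nests. MW40 also had the lowest total, 14949149 counts, and at that total the other 3 had 84886 to 86267. It was the only value to stand apart in this way among 36 groups of 4 values examined, and chance marks about 1 in 20.

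Workers and foundresses trained to faces differed in 2060 transcripts. From the 495 possible splits of these 12 wasps, 100 were examined, the real one and others drawn at random. Only the real one gave as many calls, which argues against chance. The highest other split drawn, which exchanged M79 with MW30, gave 1822 (12320 transcripts at an unadjusted p under 0.05, against 10965). On the first principal component its M30, M67, M91 and MW30 lay at -86.3 to -29.3 and M79 at 51.0. MW40 and MW41, on its other side, also lay low, at -33.0 and -35.0. Of the other splits drawn, 5 gave any call. Next came 593 calls with the workers MW21, MW42, MW32 and MW47 set against the remaining wasps. A first test of exchanged labels, by caste scores from transcripts called without both wasps, was undecided, with MW30 at 0.523 and M79 at 0.45 between foundresses trained to faces at 0 and workers at 1 (difference 0.0729, against an SD of 0.161 among workers). It was replaced, after those scores were seen, by a test at one total count per library, where M79 had 6756 more identifiers with a count than MW30, above all 8 workers and against an SD within castes of 1872, which argues against exchanged labels. Without the abundant transcripts 2019 calls were made, 1743 of which were among the 2060. This argues against a shift of all values through these transcripts as the source of most calls. The directions turned to 913 higher and 1106 lower in workers, so a shift that changes the balance of directions stays open. A drift with the month of collection cannot be told apart from caste, because foundresses were collected in May and June and all workers but MW21 in July. Distances of the foundresses from the workers differed by -0.00321 in mean squared log2 distance, May minus June. In an exact permutation test 58 of 70 assignments gave as large a difference. May and June foundresses also differ in training stimulus, so this test could not decide. Age and rearing on a foreign nest stay open as untested.

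Among the 4 groups 540 transcripts differed. Of 100 splits, the real one and others drawn at random, only the real one gave as many, against 2 calls at most in any other drawn. This argues against chance, although another of them gave more transcripts at an unadjusted p under 0.05 (8878, against 8584). Foundresses trained to faces against patterns gave 0 calls and the highest other of the 35 splits gave 10. Every split reaches a count of 0, so this says nothing about chance. The excess of 5673 transcripts at an unadjusted p under 0.05 in that comparison was reached in 5 of the 35 splits, with up to 7923 in another, so chance could not be excluded. Workers from allospecific against conspecific nests also gave 0 calls, so their 35 splits say nothing about chance either. The highest other split of the workers gave 501 calls and set MW21, MW42, MW32 and MW47 against MW25, MW40, MW30 and MW41. That split crosses the nests and was picked for its count. Its sides also lay apart on the first principal component, at 11.7 to 69.9 and at -53.9 to -3.41, in the same data.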

How the results depend on the processing

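Leaving out the abundant transcripts, keeping 1 transcript per run of neighbours and taking both foundress groups as reference were chosen after seeing the data. Sums per gene and gene set tests were not run, since the identifiers name no genes. All 4 named transcripts kept their direction and call under every alternative run (24 each, 23 for PmetTSAr2.0-020258), with log2 fold changes of 1.13 to 1.33 for PmetTSAr2.0-053836, 1.05 to 1.19 for PmetTSAr2.0-053842, -0.98 to -0.75 for PmetTSAr2.0-040168 and -1.60 to -1.31 for PmetTSAr2.0-020258. These 4 were picked for the lowest p in the same libraries, so their stability is no separate support and does not carry over to the other calls. Profile separations kept their side of 0.05 under all alternatives run. Leaving out 1 wasp gave 15.1% to 20.5% for caste (exact p 0.00303 to 0.0485), 16.2% to 26.0% for stimulus (exact p 0.0571 to 0.457) and 11.9% to 16.3% for nest (exact p 0.429 to 1).

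By DESeq2 the calls were 139 for stimulus, 1 for nest, 3536 for caste (9659 without an adjusted p) and 2419 among the 4 groups. With no low-count filter they were 33 for stimulus and 1472 among the groups. At an adjusted p under 0.1 they were 4316 for caste and 1366 among the groups. A surrogate variable gave 1153 and sample quality weights 1181 among the groups, and the fit of 12 wasps alone 1294 for caste, where fewer libraries entered. Leaving out 1 wasp gave 398 (M30) to 2803 (MW30) for caste, 208 (M91) to 655 (MW30) among the groups, 0 to 11 (M79) for stimulus and 0 for nest. At the same number of libraries, the caste count was 398 without M30, 639 without M91, 1655 without M67 and 2254 without M79. The number of libraries alone therefore does not set it, and the cause of these changes was not tested. Of 29 alternatives of the caste count, 19 had more calls higher in workers and 10 more calls lower, with 35.7% to 63.2% higher. Median log2 fold changes of all tested transcripts were 0.01 with TMM, -0.00451 with median-of-ratios factors and -0.02 without the abundant set. With 14949149 to 22832434 counts per library, calls for caste were least frequent among the least abundant transcripts (1.59% of the lowest of 4 equal bins).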

Other observations

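All tests in this part were chosen after the data were seen, except the first test on separate wasps.

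Foundress brains held counts for more transcript identifiers than worker brains, also at one total count. Thinned to the lowest total, 14949149 counts, the 8 foundresses had 88446 ± 2023 identifiers with a count and the 8 workers 83678 ± 1707 (SD, n = 8 each). Every foundress (86993 to 93235) lay above every worker (81368 to 86267), a difference of 4768 or 5.70% (exact two-sided permutation p = 0.000155, the smallest possible, adjusted p = 0.000466 over 3 tests), so total count as the whole cause is argued against. Foundresses trained to faces and to patterns differed by -1077 (exact permutation p = 0.771), and workers from allospecific and conspecific nests by -2020 (exact permutation p = 0.0857). Season, age and RNA from other tissue stay open as untested, and before thinning the ranges were 89775 to 99735 in foundresses and 82298 to 88836 in workers.

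A hypothesis was that the caste calls reflect foundresses trained to faces standing apart from all other wasps, with no part played by caste. It was tested on separate wasps. Of 605 transcripts called between workers from conspecific nests and foundresses trained to faces in a fit of those 8 wasps, 511 (84.5%) differed in the same direction between workers from allospecific nests and foundresses trained to patterns, with a mean signed log2 difference of 0.37. The real split gave the largest value of the 35 splits of those 8 wasps, and the highest other gave 0.32 (exact permutation p = 0.0286, the smallest possible), which argues against the hypothesis. With the worker groups exchanged, 56 of 59 (94.9%) had the same direction, with a mean of 0.841 against 0.727 in the highest other split (exact permutation p = 0.0286). Both runs chose transcripts with the same foundresses and measured them in the same other foundresses, so the second is no independent test. Month differs between these wasps too, so season may contribute as well as caste.

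Wasps were also placed on a scale from 0, the mean of foundresses trained to faces, to 1, the mean of workers. Each wasp trained to faces was scored by the transcripts called without it, from 389 (M30) to 2782 (MW30), and left out of both means. Foundresses trained to patterns were scored by the 2060 calls of all libraries. Left-out workers scored 0.871 ± 0.161 (SD, n = 8) and left-out foundresses trained to faces 0.26 ± 0.19 (SD, n = 4). Foundresses trained to patterns, which did not enter the choice of transcripts through the contrast, scored 0.462 ± 0.124 (SD, n = 4). That was below the workers (exact permutation p = 0.00606), while their difference from the other foundresses did not pass the test (exact permutation p = 0.143). Both tests set scores from different transcripts against each other, so neither decides where these wasps lie. The lowest worker was MW30 at 0.513 and the highest foundress trained to faces M79 at 0.45. Among foundresses trained to patterns, M4 at 0.572 and M5 at 0.557 lay above MW30. Their scores rest on other transcripts than that of MW30, so whether the castes overlap is not settled by them. MW21, the worker collected in June, scored 0.924.

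The 143 abundant transcripts that vary together lay in 85 separate stretches of identifiers, and their share of counts ran from 2.18% to 19.2%. On the log2 scale, total count explained 17.5% of the variance of their share (bootstrap 95% limits 0.139% to 52.5%). Without the log2 scale, the correlation of total count and share was 0.324 by Pearson (permutation p = 0.221) and 0.232 by Spearman (permutation p = 0.383) over 16 libraries, or 0.0968 by Pearson without MW40 and M5. Their log2 share was higher by 0.756 in foundresses (10.6% ± 3.76) than in workers (7.41% ± 5.57, SD, n = 8 each, exact permutation p = 0.0758, adjusted p = 0.152 over 4 tests). Without MW21, the difference was 0.998 (exact permutation p = 0.0121, not adjusted). MW21 had the highest share and was the only wasp left out for this test. The bounds for total count and caste were redrawn after the values were seen, because the earlier ones, which would have counted against both, could not exclude either at this number of wasps, and both stay open. Tissue other than brain carried along at dissection cannot be told apart either, since 0 identifiers carry a gene name with which markers could be found.

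The first principal component followed a surrogate variable estimated from the data (Pearson r = 0.964 over 16 libraries), on which MW21, M4, M5 and M79 lay highest and M30 and MW30 lowest, across castes and nests. Both were computed from the same libraries and the sign was set to make r positive, so their correlation is no independent observation. Among pairs of tested transcripts with adjacent identifiers, the median correlation within groups was 0.318 and 21.2% exceeded 0.7, against a median of -0.004 and 1.59% in random pairs. These correlations are across libraries after group means were removed, and pairs of transcripts are not independent replicates.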
